A study of Homo sapiens with 42 samples.

How the data were processed

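Small RNA libraries were sequenced from human brain total RNA (a purchased RNA) and from RNA of human blood plasma. Per the labels' protocols, the plasma RNA came from a kit for circulating RNA, with 1 mL as the starting volume. Adapters were ligated, the product was amplified for 4 PCR cycles and cleaned with beads. It was then digested for 2 hours with Cas9 and guide RNAs in the treatment called MAD-DASH, which cuts chosen sequences so that they do not amplify. A second PCR of 11 cycles followed, and the libraries were cleaned with beads or by gel extraction.

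The authors deposited a single table of counts, reads per mature miRNA and library, with 2041 miRNAs and 42 libraries. It is described per the labels as made after read processing. Bowtie2 2.1.0, DESeq2 and the genome build hg19 are named in the submitters' processing notes, with no role or order. The miRNA annotation and the treatment of reads that match several members of a miRNA family are not given in the sources used here. Counts of near-identical family members, such as the let-7 or miR-15/16 miRNAs, are therefore uncertain where reads could be shared. No coordinates are printed, because the reference at hand was GRCh38.

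The deposited table also holds 3 lines that name no miRNA: adapter-dimer reads, other reads too short to use, and usable reads not assigned to a miRNA. They took 40.7% to 90.3% of a library's reads and stayed out of library sizes and tests. Sums over all lines were identical for the libraries of each of the 18 groups and ranged from 1950760 to 18230060 reads between groups. How they became equal is not stated, so they are not used as a measure of sequencing depth. Shares of all reads take these sums as the total and so depend on how they became equal. Reads assigned to miRNAs ranged from 294270 to 2396262 in brain and from 1952064 to 9592307 in plasma libraries. CPM here takes the miRNA reads of the library as the total. A count of 0 allows up to 3 counts, which is 0.313 to 10.2 CPM depending on the library. Intervals for shares are 95% Wilson intervals. They and the floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

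Groups were taken from sample titles: material, cleanup, 5′ adapter (multiplex or modified) and guide set (none, adapter-dimer, miR-16, or both). Brain groups held 2 libraries and plasma groups 3. For 1 brain library the tissue fields name plasma; it was kept with its title. Brain replicates are libraries of a purchased RNA and nothing in the labels says that plasma replicates came from separate donors, so p-values measure the spread between these libraries, which may be technical. None of the 30 replicate pairs agreed within sampling noise (chi-square per degree of freedom 1.57 to 87.3), and r of log2 CPM between replicates was 0.985 to 0.995. Deviations from group means correlated between same-numbered libraries of the untreated plasma group and the plasma group labelled both guide sets at 0.39 to 0.64, a pairing read from the data and not stated in the labels. In each other comparison made within plasma at least 1 same-numbered pair correlated below 0. Even so, 16 of 18 plasma libraries correlated best with a library of their own number, so some pairing there is not excluded. Brain groups held too few pairs to tell.

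Counts were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr by group, TMM scaling, and the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. Each material was fitted with a mean per group, so that its groups shared 1 estimate of the spread. Fits across materials used all brain or all gel-extracted libraries. A common effect of the miR-16 guide set and of the adapter-dimer guide set was fitted over 3 and 6 backgrounds (material with adapter) with background as a factor. Differences between depletions were tested as contrasts. The SE given with an edgeR log2 change is its absolute value divided by the square root of the quasi-likelihood F statistic. It is an approximation, not a standard error estimated by the model. Lists of miRNAs fixed before the data were examined were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation. Of 142 distinct list names, 140 were found in the table, 21 of them under an older name. Total counts, detected miRNAs (at least 1 count after rarefaction to the smallest miRNA total of the background) and read shares were compared within backgrounds by two-sided permutation, with 100000 resamples or, over 3 backgrounds, all 720 arrangements. The 2 read-share tests were added after the table had been seen, and p-values were adjusted over the 5 tests.

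The text names miR-16-5p always. In comparisons with the miR-16 guides it names the other miR-15/16 family members and passenger strands. Per comparison it draws on up to 12 rises and 12 falls by log2 fold among miRNAs past 0.05 with a mean of at least 10 CPM and no overlap between groups, on the 10 most abundant miRNAs of each untreated multiplex group, and on up to 4 most abundant members of each list. miR-342-3p in plasma and any other miRNA named outside this rule were chosen after their values were seen.

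Each comparison was repeated with RLE size factors, without the count filter, with DESeq2 1.42.0, with only the groups compared, with the replicate number as a block, without miR-16-5p in the scaling where its guides were used, and without each library in turn. Library totals without a scaling factor were added after the data had been seen. Counts were also simulated from these libraries. There the brain bead comparison of miR-16 guides with none (475 miRNAs) recovered 72.3% of changes of 1 log2 unit and 84.8% of 2 units. The plasma comparison of adapter-dimer guides with none (974 miRNAs) recovered 46.3% and 78.5%. The simulations changed 94 and 99 of the 475 miRNAs, and 80 and 107 of the 974, by these amounts. With so many changes the adjusted threshold is easier to pass than where few miRNAs change. These rates may therefore overstate recovery in comparisons with few calls. Permutations, read shares and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.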

Results

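Small RNA libraries were made from human brain RNA with bead cleanup (12 libraries), from the same kind of brain RNA with gel extraction (12 libraries) and from plasma RNA with gel extraction (18 libraries). Each material was prepared without guides and with Cas9 guides against adapter dimer (the ligation product of both adapters with no insert), against miR-16-5p, or against both. A modified 5′ adapter was used in untreated and adapter-dimer-guide libraries. Brain groups held 2 libraries and plasma groups 3. Brain libraries held 294270 to 2396262 miRNA reads and plasma libraries 1952064 to 9592307. In untreated multiplex-adapter libraries miR-26a-5p led in brain (12.9% ± 0.224 of miRNA reads with beads and 12.6% ± 0.428 with gel, SD, n = 2), and miR-16-5p took 6.24% ± 0.498 and 6.28% ± 0.608. In plasma miR-16-5p alone took 42.1% ± 2.15 (SD, n = 3), followed by miR-26a-5p with 6.10% ± 0.498 and miR-486-5p with 3.95% ± 0.455.

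miR-16-5p, the guides' target, was depleted in every brain library labelled with miR-16 guides. In bead-cleaned brain it stood at 62416 ± 4978 CPM untreated and at 1552 ± 53.9 CPM with the miR-16 guides (SD, n = 2), a log2 change of -5.38 (SE 0.114, edgeR adjusted p = 1.51e-16), which left 2.40% of it. In gel-extracted brain it stood at 62825 ± 6085 and 1199 ± 149 CPM, a log2 change of -5.83 (SE 0.0991, edgeR adjusted p = 1.70e-13), which left 1.76%. The depletions with beads and gel differed by 0.38 on the log2 scale (SE 0.149), which did not pass the test (edgeR adjusted p = 0.991). The adjustment ran over all miRNAs tested in brain, among which miR-16-5p ranked 4 by p, so a difference is not excluded. The difference passed with no low-count filter (log2 difference 0.54, edgeR adjusted p = 7.75e-09) but not in the other 5 of 6 alternatives. Without 1 library at a time it ran from 0.26 to 0.51.

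Depletion was weaker where both guide sets were used. miR-16-5p stood at 9408 ± 1891 CPM with beads and 10664 ± 698 CPM with gel (SD, n = 2), log2 changes of -2.76 (SE 0.0985) and -2.65 (SE 0.0843) that left 14.8% and 15.9% (edgeR adjusted p = 8.33e-13 and 3.02e-10). The difference between both guide sets and the miR-16 guides alone was 2.62 (SE 0.103) with beads and 3.18 (SE 0.0886) with gel on the log2 scale (edgeR adjusted p = 3.98e-12 and 6.28e-11). With both guide sets edgeR called 3 miRNAs with beads and 2 with gel, all lower, and 7 with beads without untreated replicate 2. With gel it called 1 without untreated replicate 1 and 6 without replicate 2 of the libraries with both guide sets.

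miR-195-5p, which shares its seed with miR-16-5p, was the only other miRNA past the threshold with the miR-16 guides in brain. It fell by 1.35 (SE 0.0715) with beads, from 5328 ± 51.8 to 2164 ± 143 CPM, and by 1.30 (SE 0.0632) with gel, from 4963 ± 94.6 to 2181 ± 41.0 CPM, on the log2 scale (edgeR adjusted p = 2.40e-10 and 2.31e-08, n = 2). With both guide sets it fell by 0.35 with beads (adjusted p = 0.0138), and its log2 change of -0.29 with gel did not pass (edgeR adjusted p = 0.0811). The remaining 4 members tested, miR-15a-5p, miR-15b-5p, miR-424-5p and miR-497-5p, had log2 changes between -0.06 and 0.11 with the miR-16 guides and between -0.09 and 0.12 with both guide sets, and none passed. The passenger strands tested, miR-195-3p and miR-424-3p, did not pass either with the miR-16 guides, at 6.62 to 35.2 CPM, or with both guide sets. The count of 2 called miRNAs rose to 8 in bead-cleaned brain without untreated replicate 2 and to 5 in gel-extracted brain without untreated replicate 2.

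In plasma the target went against the labels of 6 libraries. miR-16-5p stood at 421088 ± 21491 CPM untreated and at 491936 ± 9074 CPM in the libraries labelled miR-16 guides (SD, n = 3), a log2 change of 0.20 (SE 0.0859, edgeR adjusted p = 0.119), where depletion was due. It passed, with the same direction, with RLE size factors (0.23, edgeR adjusted p = 0.0323), with no low-count filter (0.20, adjusted p = 0.00267), with miR-16-5p left out of the scaling (0.30, adjusted p = 0.00449) and without untreated replicate 1 (0.31, adjusted p = 0.0150). The libraries labelled both guide sets stood at 13232 ± 1343 CPM, a log2 change of -5.77 (SE 0.106, edgeR adjusted p = 6.38e-24) that left 1.83% with TMM scaling, or 3.14% by mean CPM with no scaling factor. The libraries labelled modified adapter without guides, in which no miR-16 guide was named, stood at 56071 ± 5059 CPM, a log2 change of -3.64 (SE 0.0953, edgeR adjusted p = 3.59e-20) against the untreated multiplex libraries, or -2.91 by mean CPM. The libraries labelled modified adapter with adapter-dimer guides stood at 491960 ± 13925 CPM. Plasma groups are named only as labelled, and directions drawn from the libraries labelled miR-16 guides or modified without guides rest on labels that the target contradicts. The difference in the miR-16-5p effect between plasma and gel-extracted brain was 6.30 on the log2 scale (SE 0.171, edgeR adjusted p = 8.10e-25) as labelled. Between the libraries labelled both guide sets and those labelled miR-16 guides in plasma it was -5.97 (SE 0.107, edgeR adjusted p = 3.51e-24), or -5.22 by mean CPM.

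**Figure D1:**
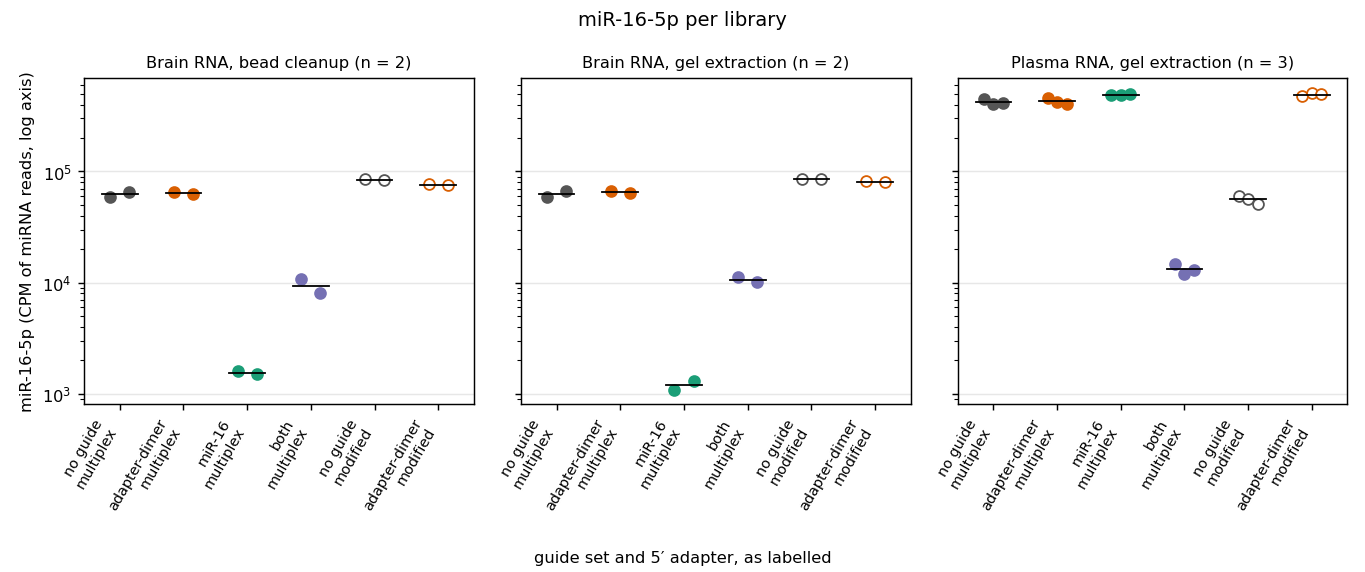
miR-16-5p in CPM of miRNA reads on a log axis, with each point a library, each bar the group mean, filled points for the multiplex and open points for the modified 5′ adapter, and colours for the guide set as labelled. Brain libraries labelled miR-16 guides lie between 1094 and 1590 CPM, while the plasma libraries labelled miR-16 guides lie between 484614 and 502088 CPM.

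Among the plasma libraries, those labelled both guide sets had miR-195-5p as the only other called miRNA besides the target (log2 change -1.34 with TMM scaling, SE 0.0928, edgeR adjusted p = 1.05e-10), at 118 ± 9.56 against 175 ± 10.6 CPM (SD, n = 3). There miR-15a-5p, miR-15b-5p, miR-424-5p and miR-497-5p had log2 changes between -0.14 and 0.06, and none passed, nor did the passenger strands tested (miR-16-2-3p, miR-15b-3p, miR-195-3p, miR-424-3p and miR-497-3p). The libraries labelled miR-16 guides differed from the untreated ones in 193 of 1046 miRNAs, 72 higher and 121 lower. Of the miR-15/16 family, miR-15b-5p (0.81, SE 0.0488), miR-195-5p (0.97, SE 0.0871), miR-15a-5p (0.76, SE 0.0715), miR-424-5p (0.43) and miR-497-5p (0.40) were higher there on the log2 scale, and the passenger strand miR-15b-3p was lower, at 0.366 against 6.29 CPM, while miR-16-2-3p, miR-195-3p, miR-424-3p and miR-497-3p did not pass. miR-200b-3p (2.45), miR-370 (1.86), miR-369-3p (1.77) and the neutrophil-rich miR-223-3p (1.04) were also higher, and miR-423-3p (-3.43), miR-340-3p (-3.25) and miR-142-5p (-2.52) lower, with edgeR adjusted p at most 1.63e-08 for these 7. Without a scaling factor the libraries labelled both guide sets gave 450 calls in place of 2, 448 of them higher.

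Adapter-dimer guides lowered the adapter-dimer share in brain. The share fell from 10.3% ± 8.34 to 1.59% ± 0.321 with beads and the multiplex adapter, from 19.1% ± 5.66 to 0.787% ± 0.0231 with beads and the modified adapter, from 0.333% ± 0.162 to 0.0375% ± 0.0131 with gel and the multiplex adapter, and from 1.04% ± 0.361 to 0.0325% ± 0.00543 with gel and the modified adapter (SD, n = 2). In plasma it stood at 5.09% ± 3.34 untreated and 0.894% ± 0.990 with the guides on the multiplex adapter (SD, n = 3). In the libraries labelled modified it stood at 1.51% ± 1.58 without guides, a label that miR-16-5p contradicts, and 1.66% ± 1.26 with guides. It stood at 4.83% ± 3.28 in the plasma libraries labelled both guide sets and at 20.4% ± 9.77 in those labelled miR-16 guides. In brain it stood at 1.35% ± 0.734 with beads and 0.0593% ± 0.0232 with gel for both guide sets, and at 17.1% ± 16.8 and 0.330% ± 0.0200 for the miR-16 guides. Over the 6 backgrounds the mean log2 ratio was -2.94 (two-sided permutation p = 0.000250, adjusted p = 0.000625). The ratio was -2.42 to -4.97 in 5 of them and 0.30 in the plasma background labelled modified, whose untreated label miR-16-5p contradicts. Untreated replicates differed widely, at 4.38% (95% Wilson interval 4.363 to 4.399) and 16.2% (16.1 to 16.2) in bead-cleaned brain with the multiplex adapter.

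**Figure D2:**
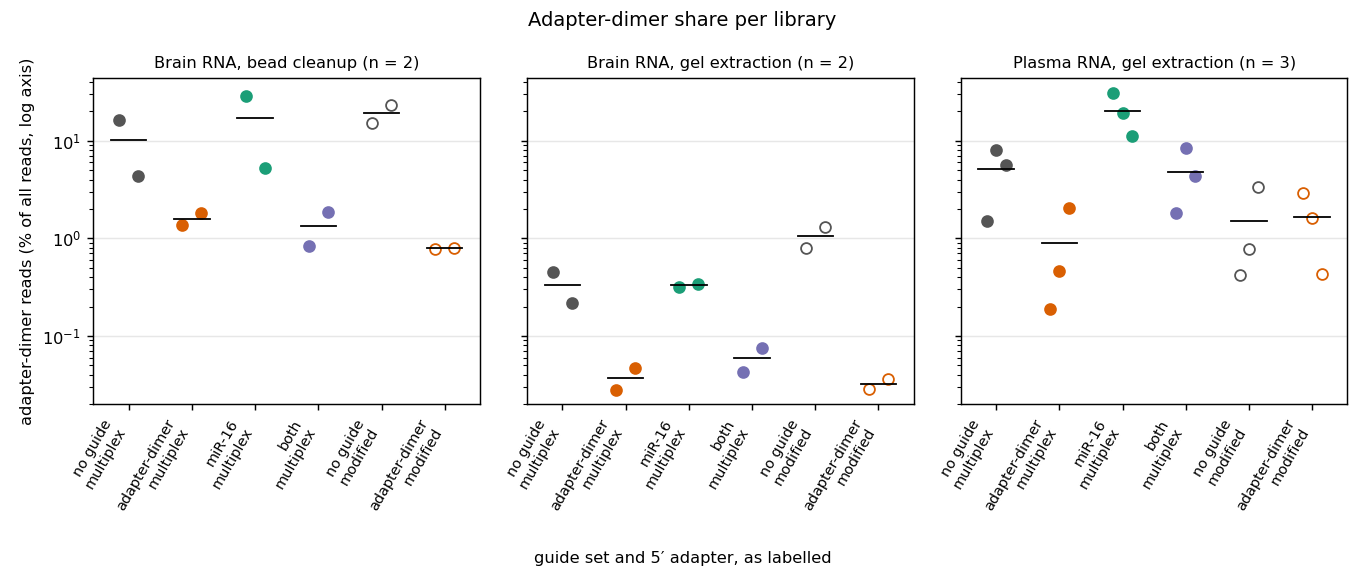
Adapter-dimer reads as percent of all reads on a log axis, with each point a library, each bar the group mean, filled points for the multiplex and open points for the modified 5′ adapter, and colours for the guide set as labelled. In each brain panel the libraries with adapter-dimer guides lie below the untreated libraries of the same adapter.

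Among the miRNAs themselves, miR-125b-1-3p was the only one past the threshold with adapter-dimer guides on the multiplex adapter in brain. It fell by 0.95 (SE 0.131) with beads, from 172 ± 9.21 to 84.7 ± 1.51 CPM, and by 1.17 (SE 0.129) with gel, from 175 ± 15.99 to 77.8 ± 11.5 CPM, on the log2 scale (edgeR adjusted p = 0.000737 and 0.000476, n = 2). With both guide sets it fell by 0.94 and 0.93, against the same untreated libraries. miR-16-5p stood at log2 changes of 0.12 with beads, 0.06 with gel and 0.05 in plasma with adapter-dimer guides, and did not pass. The call with beads was lost when only the groups compared were fitted, and 4 miRNAs were called with beads without untreated replicate 1 or without replicate 2, and 2 with gel without untreated replicate 2. In plasma on the multiplex adapter edgeR called 0 of 1046 miRNAs, with 36 at an unadjusted p under 0.05 and 0 calls with DESeq2.

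On the modified adapter other miRNAs were called with the adapter-dimer guides in brain, most of them lower. Whether the effect of the guides differed between the adapters was not tested. miR-342-3p fell by 2.75 (SE 0.0968) with beads, from 1975 ± 76.5 to 300 ± 17.6 CPM, and by 2.42 (SE 0.134) with gel, from 1640 ± 110 to 310 ± 2.40 CPM, on the log2 scale (edgeR adjusted p = 6.59e-13 and 1.98e-07). miR-487a (-1.82 and -1.47), miR-154-5p (-1.30 and -1.41), miR-484 (-0.88 and -0.90), miR-92a-3p (-0.72 and -0.67) and miR-100-5p (-0.35 and -0.41) also fell in both cleanups, while miR-16-5p, at -0.18 and -0.09, did not pass. In all 13 miRNAs were called with beads, none of them higher, and 8 with gel, of which miR-181b-5p (0.37) and miR-23b-3p (0.21) were higher. Of 13 and 6 lower calls among 459 miRNAs tested in both, 6 were shared, where independent lists would share 0.170 (Fisher's exact test, one-sided, p = 1.37e-10). That p takes the cleanups as independent, while same-numbered bead and gel libraries may share a preparation, which was not tested. With beads 7 and 4 were called without untreated replicates 1 and 2 and 6 and 7 without guide replicates 1 and 2, and with gel 5 without either untreated and 4 without either guide replicate. The counts reached 109 and 18 with no low-count filter. In plasma the libraries labelled modified adapter with adapter-dimer guides differed from those labelled modified without guides in 270 of 1046 miRNAs, 110 higher and 160 lower, among them miR-16-5p (3.87, SE 0.0964, or 3.13 by mean CPM), and without a scaling factor in 564. miR-16-5p contradicts the label of the second group, so no effect of the guides is read from that count.

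The modified 5′ adapter gave a different miRNA profile from the multiplex adapter in untreated brain libraries. edgeR called 178 of 494 miRNAs with beads (75 higher, 103 lower) and 170 of 467 with gel (56 higher, 114 lower, or 82 and 100 with RLE size factors and 91 and 100 without a scaling factor). miR-369-3p (2.42 and 2.27), miR-200b-3p (2.63 and 2.05) and miR-370 (1.85 and 1.96) were higher with the modified adapter, and miR-409-5p (-2.61 and -2.95), miR-153 (-2.45 and -2.69), miR-423-3p (-2.55 and -2.85) and the neuronal miR-218-5p (-2.63 and -2.52) lower, with beads and gel in that order. miR-16-5p was higher by 0.38 and 0.32. Of 130 miRNAs called in both cleanups, 129 had the same direction. Higher calls shared 43 miRNAs where independent lists would share 9.15, and lower calls 86 where they would share 24.8. No library is common to both comparisons, but same-numbered bead and gel libraries may come from the same preparations, which was not tested. The cleanups may therefore not be independent repeats.

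By list, all 5 other members of the miR-15/16 family tested rose with the modified adapter in both cleanups, among them miR-195-5p (0.99 and 0.96) and miR-15a-5p (0.57 and 0.61). Of the let-7 family, broadly expressed miRNAs of differentiation, 7 of 9 fell and 2 rose in each, with let-7f-5p at -0.71 and -0.76 and let-7g-5p at -0.69 and -0.73. Adjusted over each list alone, the counts of these 2 lists were the same. camera adjusted p at the preset correlation was 0.000185 and 0.000467 for the miR-15/16 list and 0.00725 and 0.0138 for let-7, while with an estimated correlation adjusted p was 0.356 and 0.0575, and 0.534 and 0.527. Of 20 neuronal miRNAs 4 rose and 11 fell with beads, and 3 rose and 12 fell with gel (camera adjusted p = 0.134 and 0.0441, adjusted p = 0.534 and 0.369 with an estimated correlation), with miR-9-5p at 0.49 and 0.53. Of the leukocyte and platelet list 4 rose and 6 fell with beads and 2 rose and 4 fell with gel, where miR-126-3p stood at -1.72 and -1.74, miR-21-5p at -1.54 and -1.43 and miR-223-3p at 1.03 and 0.81. That list did not pass (camera adjusted p = 0.471 and 0.523, adjusted p = 0.534 and 0.527 with an estimated correlation). The plasma libraries labelled modified and multiplex without guides differed in 1 miRNA, miR-16-5p, or in 452 without a scaling factor. miR-16-5p contradicts the label of those labelled modified, so no effect of the adapter in plasma is read from these counts.

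**Figure D3:**
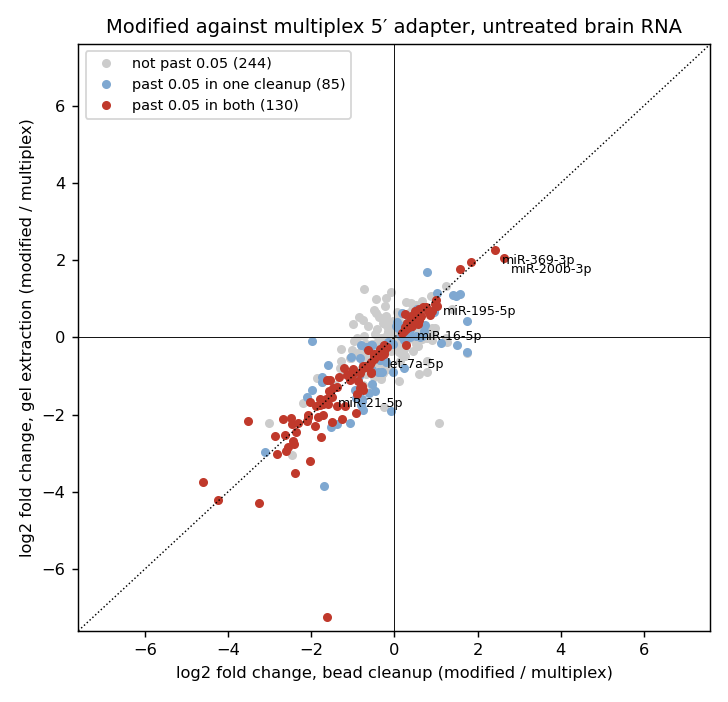
Log2 fold changes of 459 miRNAs between the modified and multiplex 5′ adapter in untreated brain RNA, with bead cleanup on the x axis and gel extraction on the y axis, each point a miRNA and colours by edgeR adjusted p. Of the 130 miRNAs past 0.05 in both cleanups, 129 lie in the quadrants of equal sign, while folds of miRNAs near 0 counts depend on the prior count.

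Between bead cleanup and gel extraction of untreated brain libraries with the multiplex adapter, miR-9-3p, a neuronal miRNA, was the only call of 501, higher with beads by 0.27 (SE 0.0497), at 22446 ± 44.7 against 18570 ± 271 CPM (SD, n = 2, edgeR adjusted p = 0.0140), and 38 miRNAs had an unadjusted p under 0.05. miR-16-5p stood at -0.02 and did not pass. The test took the libraries as unpaired, and whether same-numbered bead and gel libraries share a preparation was not tested. The call of miR-9-3p was lost with only the groups compared and without bead replicate 2, gel replicate 1 or gel replicate 2, and 2 miRNAs were called without bead replicate 1. No list had more than 1 member called. let-7 had a camera adjusted p of 0.00183 with a median log2 difference of -0.09, and adjusted p was 0.846 with an estimated correlation. Bead-cleaned libraries with adapter-dimer guides differed from untreated gel-extracted ones in miR-9-3p (0.28) and miR-125b-1-3p (-1.05) on the multiplex adapter, where miR-16-5p, at 0.04, did not pass. On the modified adapter they differed in 15 miRNAs, 2 higher and 13 lower, among them miR-342-3p (-2.52, SE 0.115), miR-487a (-1.90, SE 0.163) and miR-154-5p (-1.47, SE 0.136) but not miR-16-5p (-0.23), and in 7 without replicate 2 or 9 without replicate 1 of the bead-cleaned guide libraries. Without a scaling factor 10 were higher and 12 lower.

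Plasma and brain differed in most miRNAs. Between untreated, gel-extracted multiplex libraries edgeR called 656 of 985 miRNAs, 375 higher and 281 lower in plasma, and miR-16-5p was higher by 3.61 (SE 0.127, edgeR adjusted p = 6.65e-23). All 20 neuronal miRNAs tested fell, with miR-124-3p at 5.997 ± 2.69 CPM in plasma (n = 3) and 56728 ± 19.7 CPM in brain (n = 2), a log2 change of -12.39 (SE 0.347), and miR-9-5p at -11.29 (SE 0.262). All 4 oligodendrocyte miRNAs fell, with miR-338-3p at -7.14 (SE 0.132). The liver miRNA miR-122-5p stood at 12949 ± 734 CPM in plasma and 6.45 ± 1.41 CPM in brain (log2 change 11.84, SE 0.178). These edgeR adjusted p were at most 1.09e-25.

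Blood cell miRNAs were higher in plasma. Of 15 erythrocyte miRNAs 14 rose, with miR-486-5p at 7.02 (SE 0.238) and miR-451a at 5.64 (SE 0.403), and of 14 leukocyte and platelet miRNAs 12 rose and 1 fell, with miR-223-3p at 7.28 (SE 0.117) and miR-21-5p at 3.32. All 13 members of miR-17-92 and its paralog clusters rose, with miR-106b-5p at 3.84. Of 6 liver miRNAs 4 rose and 1 fell (miR-885-5p, -4.73). camera adjusted p with an estimated correlation was 0.000232 for the neuronal, 0.00238 for the oligodendrocyte, 0.000406 for the erythrocyte and the leukocyte and platelet, 0.00372 for the miR-17-92 and 0.0328 for the liver list. Of the imprinted 14q32 cluster 32 of 42 fell and 5 rose, with miR-487b at -2.36 and miR-409-3p at 1.31 (camera adjusted p = 9.46e-06, adjusted p = 0.0923 with an estimated correlation). let-7 members went both ways (4 rose, 5 fell), as did the other miR-15/16 members (3 rose, 2 fell, miR-15b-5p 4.34 and miR-195-5p -3.97), their passenger strands (3 rose, 1 fell) and the striated muscle list (1 rose, 2 fell), with camera adjusted p of 0.427, 0.659, 0.410 and 0.659. Adjusted over the list alone the counts were the same except for 6 in place of 5 rises in the 14q32 cluster. The median log2 difference of all miRNAs was 0.66 with TMM and 0.74 with RLE, and without a scaling factor it was -0.17 with 243 higher and 362 lower.

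**Figure D4:**
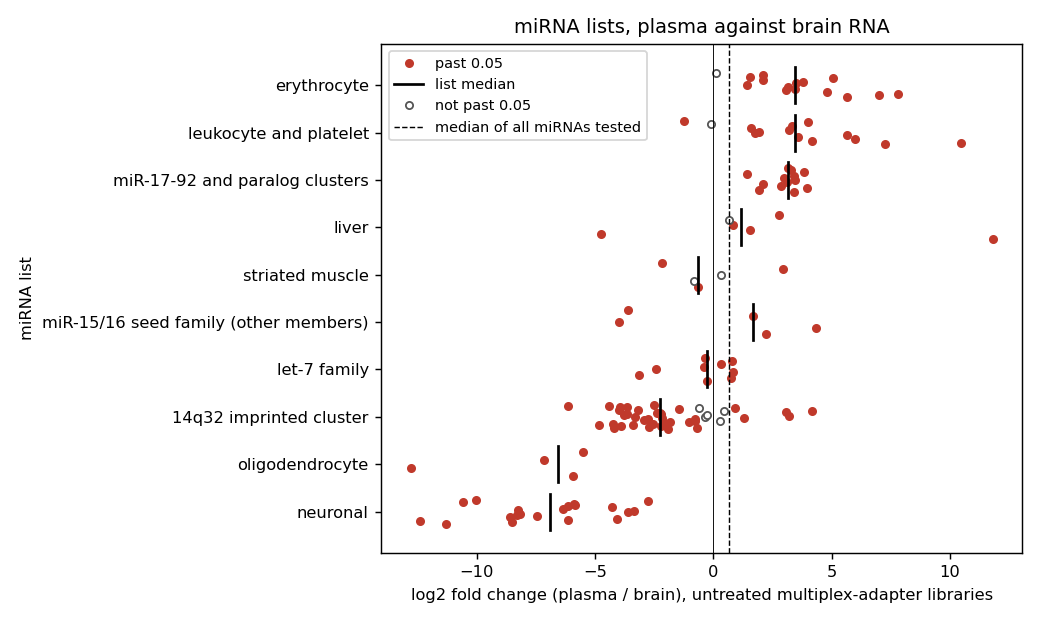
Log2 fold changes between untreated plasma and brain libraries (gel extraction, multiplex adapter) for the members of 10 miRNA lists, each point a miRNA, filled where edgeR adjusted p was under 0.05, with the list median as a bar and the median of all 985 miRNAs as a dashed line. The 20 neuronal miRNAs lie below 0 and 14 of 15 erythrocyte miRNAs above it, and miR-223-5p, with 0 counts in both brain libraries, is drawn at a fold that depends on the prior count.

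Over all backgrounds the adapter-dimer guides went with more miRNA reads. The mean log2 ratio of total miRNA counts was 1.28 (permutation p = 2.00e-05, adjusted p = 0.0001) and was above 0 in 6 of 6 backgrounds. The sums over all reads were equal within and unequal between groups, so this ratio also carries how the libraries were sampled. Libraries of a group are not independent in it, and its permutation p cannot be read as an effect of the guides. Of the 1.28, the miRNA share of all reads gave 0.35, and the rest was the ratio of those sums. That share takes the sums as its total, so its test also depends on how they became equal. The share of miRNA reads among all reads rose by a mean of 0.35 on the log2 scale (permutation p = 0.00152, adjusted p = 0.00253, higher in 6 of 6 backgrounds), of which the plasma libraries labelled modified gave 1.09 and gel-extracted brain 0.07 and 0.01. Without those plasma libraries the mean was 0.20 (permutation p = 0.0292), and without all plasma libraries 0.18 (permutation p = 0.128). Detected miRNAs, rarefied to equal miRNA totals, differed by a mean of -39.9 (permutation p = 0.0117, adjusted p = 0.0147), of which the plasma libraries labelled modified gave -188 and without which the mean was -10.3 (permutation p = 0.233). Not rarefied, the mean was 215.8 more. For the miR-16 guides the difference was -12.3 (exact permutation p = 0.411), at 34.9 in bead-cleaned brain, -19.5 in gel-extracted brain and -52.2 in plasma as labelled.

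A common effect of the miR-16 guides over brain and plasma, with labels that the plasma target contradicts, gave 56 of 552 calls (44 higher, 12 lower, or 40 and 19 with RLE size factors), with miR-16-5p at -3.27 (SE 1.15, edgeR adjusted p = 0.0660). miR-625-3p (1.20, SE 0.184), miR-374b-5p (0.50) and miR-27a-3p (0.49) were higher with all libraries, as was miR-15b-5p of the miR-15/16 family (0.64, SE 0.190), while miR-15a-5p (0.59), miR-424-5p (0.41), miR-497-5p (0.38), miR-195-5p (-0.14) and the passenger strands miR-16-2-3p, miR-195-3p and miR-424-3p did not pass. No call of a higher miRNA was left without the plasma libraries, where 2 miRNAs were called, both lower, and the count ran from 6 to 135 without any 1 of the 14 libraries, each of which moved it by over 1.5 times. The adapter-dimer guides gave 158 of 872 calls (150 higher, 8 lower), among them miR-195-5p (0.57, SE 0.0922) and miR-16-5p (0.90, SE 0.288, edgeR adjusted p = 0.0271). With RLE size factors 3 miRNAs were called, all lower, and 0 were called without the plasma libraries or without those labelled modified. All 5 other miR-15/16 members rose with TMM (camera adjusted p = 1.43e-07, adjusted p = 0.0937 with an estimated correlation), as did 11 of 20 neuronal miRNAs (camera adjusted p = 0.000800, adjusted p = 0.445 with an estimated correlation), beside a median shift of all miRNAs of 0.13.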

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

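All tests in this part were chosen after the values they bear on had been seen, except the differences between depletions and the counts over other splits of the libraries, which were fixed before the data were examined.

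The miR-16-5p effect differed between plasma and gel-extracted brain by 6.30 on the log2 scale as labelled, and in plasma the libraries labelled both guide sets differed from those labelled miR-16 guides by -5.97 (-5.22 by mean CPM with no scaling factor), where in 6 plasma libraries the target went against the guides named. That the guides cut in no plasma library is argued against, since the lowest, labelled both guide sets, lay at -5.13 (log2) from the untreated mean. A failed digestion of only the libraries labelled miR-16 guides is not tested by that value. Poor capture by the modified adapter is argued against. miR-16-5p was higher by 0.23 (log2) in the libraries labelled modified with adapter-dimer guides than in the untreated multiplex libraries. It was also higher with the modified adapter in brain. A score of the adapter, made from 122 miRNAs that differed between adapters in both brain cleanups without miR-16-5p, put 6 of the 6 libraries labelled miR-16 guides or modified without guides on the side opposite to their adapter label. The group means were 0.844 for the libraries labelled miR-16 guides and 0.00836 for those labelled modified without guides, against 0.823 for the libraries labelled modified with adapter-dimer guides, but 9 other plasma libraries set the zero or the midpoint of the score by their labels, so that their own sides test nothing. An exchange of labels among 3 plasma groups is a candidate explanation. Libraries labelled miR-16 guides may be the modified untreated ones. Those labelled both guide sets may have had miR-16 guides alone, and those labelled modified without guides may have had both. In the deposited table the plasma columns stood in another order of labels than the brain columns. Reading the plasma columns in the brain order would give this exchange. The numbers in the plasma library names rose in the order of the labels instead. Adapter-dimer shares were 4.83% ± 3.28 in those labelled both guide sets and 5.09% ± 3.34 in untreated multiplex libraries (SD, n = 3). They were 1.51% ± 1.58 in those labelled modified without guides and 0.894% ± 0.990 with adapter-dimer guides on the multiplex adapter. Libraries labelled miR-16 guides had 20.4% ± 9.77. These spreads are wide, and the exchange was not tested on these shares. By mean CPM, libraries labelled both guide sets kept 3.14% of untreated miR-16-5p, and those labelled modified without guides 13.3%. Brain libraries kept 2.49% (beads) and 1.91% (gel) with miR-16 guides, and 15.1% and 16.97% with both. With TMM scaling the plasma log2 changes were -5.77 and -3.64. Those in brain were -5.38 and -5.83, and -2.76 and -2.65. The order is the one the exchange would give, which was not tested. No source used here settles the exchange.

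In brain the depletion with both guide sets was weaker than with the miR-16 guides alone, by 2.62 on the log2 scale with beads and 3.18 with gel. Reads carried over from other libraries at similar rates are argued against, since the share of all reads that was miR-16-5p was higher with both guide sets by at least 3.01 on the log2 scale in each cleanup. Competition between guides in 1 reaction may still be a cause. The adapter-dimer share with both guide sets did not differ past the threshold from that with adapter-dimer guides alone (log2 differences -0.34 with beads and 0.65 with gel, exact permutation p = 0.778 over 36 arrangements), which decides nothing at this number of libraries. No biological explanation was tested, since both groups hold the same purchased RNA.

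The common effect of adapter-dimer guides called 158 miRNAs, nearly all higher. Both explanations tested could contribute to it: 3 were called with RLE size factors, and 0 without the plasma libraries labelled modified, where the labels are in doubt. The count also fell, but not to 0, without the bead-cleaned or without the gel-extracted brain libraries. A fall on leaving out libraries is therefore not in itself specific to those labels. Of the fits that left out a background, only those without the plasma libraries labelled modified gave 0 calls. These explanations are not exclusive, since a misplaced group can also move the scaling. Of 100 splits within backgrounds 1 gave as many calls, the real one, and the highest of the others gave 14, which argues against chance but not against those explanations.

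For the common effect of miR-16 guides, 5 of 100 splits gave at least the 56 calls of the real one, with 84 as the highest of the others, so chance cannot be excluded. The plasma comparisons of 3 with 3 libraries allow 10 splits, too few for a share under 0.05. The real split gave 193 calls for the libraries labelled miR-16 guides, 2 for those labelled both guide sets, 270 for the adapter-dimer guides on the adapter labelled modified and 1 for the adapters as labelled, each the 1 split of the 10 with as many, with 0 as the highest of the others. For adapter-dimer guides on the multiplex adapter all 10 splits gave 0.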

How the results depend on the processing

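Library totals without a scaling factor, the alternatives of the read shares and the fit without the plasma libraries labelled modified were chosen after the data had been seen. Of 38 results 16 were the same, in direction and side of the threshold or within 1.5 times of a count, under the alternatives run. So were 193 of 239 values under alternatives and 277 of 315 values without 1 library, and 2 values reversed. Of 3481 values of 288 called miRNAs named by rule, 3117 kept direction and call, 358 lost the call and 6 reversed (common effect of adapter-dimer guides without plasma). Where no value below shows it, the cause was not tested. A library left alone in its group was assumed to vary like the other groups, and depth limits what miRNAs near the floor of 0.313 to 10.2 CPM can show.

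With no low-count filter, the called miRNAs in bead-cleaned brain were 4 in place of 2 for miR-16 guides, 5 in place of 3 for both guide sets, 4 in place of 1 for adapter-dimer guides and 109 in place of 13 for these on the modified adapter. In gel-extracted brain they were 5, 6, 3 and 18 in place of 2, 2, 1 and 8. Between untreated beads and gel they were 2 in place of 1, and the difference between the depletions of miR-16-5p with beads and gel passed at 0.54. With only the groups compared, adapter-dimer guides gave 0 calls with beads (edgeR, 25 at an unadjusted p under 0.05 in the whole fit), both guide sets 1 with gel, and adapter-dimer guides on the modified adapter 18 with gel. Untreated beads against gel gave 0, and bead-cleaned guide libraries against untreated gel gave 1 on the multiplex and 27 on the modified adapter, in place of 1, 2 and 15. With DESeq2 the first of these gave 3 and the second 6.

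For the common effect of miR-16 guides, 56 calls became 95 with DESeq2, 95 without the bead-cleaned brain, 112 without the gel-extracted brain, 2 without the plasma libraries and 16 without a scaling factor. For the common effect of adapter-dimer guides, 158 became 3 with RLE size factors, 63 with DESeq2, 56 without the bead-cleaned and 27 without the gel-extracted brain, 4 without a scaling factor, and 0 without the plasma libraries or without those labelled modified (edgeR, 235 at an unadjusted p under 0.05 with all libraries). Without a scaling factor the plasma libraries labelled both guide sets gave 450 in place of 2, those labelled modified with adapter-dimer guides 564 in place of 270, the adapters as labelled 452 in place of 1, and untreated beads against gel 2. With an estimated correlation 6 of 74 list tests passed in place of 16.

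miR-16-5p in the plasma libraries labelled miR-16 guides passed at a log2 change of 0.23 with RLE size factors, 0.20 with no low-count filter and 0.30 with miR-16-5p left out of the scaling. The difference in detected miRNAs for adapter-dimer guides was -10.3 without the plasma libraries labelled modified and reversed to 215.8 when not rarefied, since deeper libraries detect more. For the miR-16 guides it passed at -35.8 without the bead-cleaned brain and reversed to 7.70 without plasma. The miRNA share rose by 0.18 (log2) without plasma and did not pass.

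Without 1 library at a time, calls ran from 2 to 8 for miR-16 guides, 2 to 7 for both guide sets, 1 to 4 for adapter-dimer guides and 4 to 7 for these on the modified adapter in bead-cleaned brain. They ran from 2 to 5, 1 to 6, 1 to 2 and 4 to 5 in gel-extracted brain, from 0 to 2 between untreated beads and gel, and from 1 to 2 and 7 to 15 for bead-cleaned guide libraries against untreated gel on the multiplex and modified adapters. They ran from 6 to 135 for the common effect of miR-16 guides, and miR-16-5p in the plasma libraries labelled miR-16 guides ran from 0.14 to 0.31 and passed without untreated replicate 1.

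Deviations of same-numbered libraries correlated at -0.40 to 0.23 in bead-cleaned brain and -0.70 to 0.30 in gel-extracted brain, where 4 of 12 and 4 of 12 libraries correlated best with their own number. In plasma 16 of 18 did, but the correlations ran from -0.43 to 0.75, and every same-numbered pair was over 0.1 in 3 of 15 pairs of groups. For the untreated libraries and those labelled both guide sets, 1 of these 3, the block left 2 calls. With the replicate block, untreated beads against gel gave 0 calls in place of 1 and the common effect of miR-16 guides 0 in place of 56 (edgeR, 38 and 200 at an unadjusted p under 0.05 without the block, 3 and 95 calls with DESeq2), and miR-16-5p in the plasma libraries labelled miR-16 guides passed at 0.21. The block moved no other count by over 1.5 times and no other call of miR-16-5p.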

Other observations

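The comparisons of plasma with brain in this part were chosen after the plasma values had been seen. Of the remaining lists in the comparison of the modified with the multiplex adapter in brain, with beads and gel in that order, the imprinted 14q32 cluster had 4 higher and 12 lower members of 39 and of 40, with miR-487b at -0.11 with beads. Erythrocyte miRNAs had 2 higher and 4 lower with beads and 0 higher and 5 lower of 12 with gel. miR-17-92 and its paralogs had 6 higher and 1 lower, and 2 higher and 1 lower, of 12. Of 4 oligodendrocyte miRNAs 1 was higher with beads, and 1 higher and 1 lower with gel, while 2 of 3 liver miRNAs and 1 of 3 striated muscle miRNAs were lower in each. None of these lists passed, with camera adjusted p of at least 0.181 at the preset and 0.369 with an estimated correlation.

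The comparison of the plasma libraries labelled miR-16 guides with the untreated ones shares its pattern with the brain comparison of the modified with the multiplex adapter. Of 109 miRNAs called in both that plasma comparison and the bead-cleaned brain comparison, 109 had the same direction, and so did 108 of 108 with gel-extracted brain. Higher calls shared 40 miRNAs with bead-cleaned brain where independent lists would share 10.1, and lower calls 69 where they would share 21.1. These comparisons have no library in common.

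Values of miR-342-3p, which fell in brain with adapter-dimer guides on the modified adapter, were also low in the plasma libraries labelled modified with adapter-dimer guides, at 118 ± 31.1 CPM against 1282 ± 248 CPM in those labelled modified without guides (SD, n = 3), a log2 change of -2.71 with TMM scaling (SE 0.190). The labels of the second group are in doubt, so this difference is given as a value only.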
